A study of Staphylococcus aureus with 2 samples.

How the data were processed

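RNA of Staphylococcus aureus HG001 exposed or not exposed to GB-AP-238 was hybridised to 2 two-colour arrays. Per the labels' protocols, cells were stabilised, broken with beads and extracted on silica columns with a DNase step, and the dyes were incorporated during reverse transcription. The unexposed RNA was labelled with cyanine 3 (green) and the exposed RNA with cyanine 5 (red) on both arrays, per the labels. Per the file headers, the authors quantified the scans with Agilent Feature Extraction version 9.5.1.1, and both arrays came from 1 slide scanned at 1 time, so that no slide or scan batch could be compared. The deposited scanner files give the raw mean signal intensity and the local background intensity of each spot in each channel. They also give processed intensities, to which background subtraction with spatial and multiplicative detrending and a dye normalization with lowess had been applied, per the file headers. The deposited log10 ratio is red over green of the processed signals, that is exposed over unexposed, and the deposited p-value comes from the scanner software's error model. The authors' table of the whole series holds the same log10 ratio: all 15600 of its values on each array equalled those in the scanner files, with medians of 0.0001485 and 0. Its scale, direction and centring are therefore known.

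The ratios reported here were computed from the raw intensities in R 4.3.3 with limma 3.58.1. Background was corrected with normexp and an offset of 50 on the mean signal and the median local background. Each array was then normalized by loess, in which control spots had a weight of 0. The loess curve sets the middle of the ratios to 0 at each brightness, so every ratio is relative to the typical probe, and the offset pulls the ratios of dim probes toward 0. Each sample probe had 1 spot per array. The 50 probes flagged as non-uniform or population outliers on either array were left out. A further 1278 probes were left out because neither channel was well above background on both arrays. The remaining 13736 probes were tested on log2(exposed over unexposed) with lmFit, intercept only, and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each array counted as 1 replicate. Saturated spots were kept. Levels per channel, used to compare the same kind of RNA between arrays and for lower bounds, were taken after loess and Aquantile normalization and are open to dye bias, since no array had the dyes exchanged. A probe not well above background in 1 channel on both arrays was given the bound of the brighter mean level over the higher of its own level and the lowest level well above background on each array.

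The prior of the variance model, with 7.85 degrees of freedom and an SD of 0.21 log2 units, dominates each probe's own estimate. The test was checked on simulated data: in 20 simulations of the comparison with 13736 probes, 200 of them changed, it recovered a mean of 26.8% of 1.5-fold, 93.7% of 2-fold, 99.9% of 3-fold and 99.9% of 4-fold changes. The share of wrong calls ranged from 1.45% to 24.3%, and the estimated prior degrees of freedom from 5.71 to 37.4, although 7.85 had been put in. A limit of 10% wrong calls, set first, was exceeded by the first simulation at 24.3%. The number of simulations was then raised to 20 and a limit of 15% set on their mean, so the nominal 5% is not held. The simulations had far fewer changed probes than the real data, for which the share of wrong calls is not known. The spread of log2 ratios between spots of 1 control probe within an array had a median SD of 0.11 over the 10 E1A control probes, and the SD between the arrays had a median of 0.15 over the tested probes. The arrays did not hold identical values, as the untreated level differed at least 4-fold between them at 51 probes and the treated level at 38.

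Before the data were examined, 40 gene lists of pathways and regulons were fixed for testing. They were not tested, because 0 of the probe identifiers matched a gene in the files or in the reference table, and gene identities were not analysed here. For the same reason the planned rule on several probes of a gene was not applied, and counts of genes became counts of probes. The rule for named features, also fixed beforehand, took the 15 probes with the largest and the 15 with the most negative mean log2 ratio among those past the threshold with the same sign on both arrays. As the identifiers name no gene, the first 2 of each are printed and the rest are summarised. Probes at least 2-fold changed on both arrays were counted without a test. The alternatives fixed beforehand were no background subtraction, the processed log ratio, the series table, an offset of 10, median centring, no filter, a filter on both channels, an intensity trend with a robust prior, a 2-fold limit and each array alone. Centring on control probes, the share called by brightness under other backgrounds, leaving out probes with a saturated spot and the scanner software's own p-value were added after the data were seen.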

Results

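The response of Staphylococcus aureus HG001 to the compound labelled GB-AP-238 was measured on 2 two-colour Agilent oligonucleotide arrays. HG001 is a laboratory strain in which rsbU, a gene for an activator of the stress sigma factor SigB, has been repaired. Per the labels, cells had grown in Mueller-Hinton broth, a rich medium, to an optical density of 0.6 to 0.8 at 600 nm. Each array set the RNA of exposed cells, in cyanine 5, against the RNA of unexposed cells, in cyanine 3, so that the design holds 1 comparison with 2 replicates. The dose and the exposure time are not given in the sources used here. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these arrays. The dyes ran the same way on both arrays, and a difference in how a probe takes up the dyes therefore stands in every ratio beside the effect of the compound.

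The arrays carried 15064 sample probes and 536 control spots each. The median probe signal of the unexposed RNA was 1440 on replicate 1 and 1160 on replicate 2, over median local backgrounds of 43 and 42.5. The median signal of the exposed RNA was 564 and 549, over a background of 71 on both arrays. The unexposed RNA gave a signal well above background at 94.1% and 91.5% of the probes, and the exposed RNA at 86.3% and 85.5%. Saturation touched 203 and 185 probes in the unexposed channel and 45 and 51 in the exposed channel. The number of arrays limits the precision. The reference table for this species lists 2872 genes, so there were more probes than genes and several probes can read 1 transcript. None of the probes carried a gene name, a description or a position, and no probe identifier matched that table. All counts below are therefore counts of probes, not of genes.

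The comparison asked which transcripts changed in abundance on exposure to GB-AP-238. A large part of the tested probes passed the threshold. In this count a dye difference of a probe cannot be told apart from a change of its transcript. Of 13736 probes tested, 4502 were higher in exposed cells and 4693 were lower, which are 32.8% and 34.2% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05). Of the 9195 probes past this threshold, 9192 had the same sign on both arrays. The median log2 ratio was 0.79 among the higher probes and -1.04 among the lower ones. Most changes were moderate, as 5181 of the probes past the threshold changed by less than 2-fold.

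Decreases of at least 2-fold were more common than increases of that size. On both arrays, 1253 probes were at least 2-fold higher and 2102 were at least 2-fold lower. Decreases made up 62.7% of these. At 8-fold the counts were 78 higher and 135 lower, at 16-fold they were 16 and 22, and at 32-fold they were 10 and 3. These counts take the median probe as unchanged. Centred on 10 probes whose identifiers carry the tag Ctrl16S, an added setting, the median of all tested log2 ratios lay at -0.45, and 1825 probes were higher and 6788 lower. The prior of the variance also changed in that fit, and with the same shift on both arrays, which leaves the variances as they were, 2087 were higher and 7348 lower. Centred on the 10 E1A control probes the median of all tested log2 ratios lay at -0.58, and the counts were 1683 and 8144. The labels do not mention RNA added for the E1A probes, and only 5 of them were above every negative control spot. Their log2 ratios had an SD of 0.42 over the probes. Neither set is known to be unchanged. In the other direction, adding 0.17 to every log2 ratio would even the 2-fold counts.

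At 10 probes the increase exceeded 32-fold on both arrays. The probe V7_6689 rose by 6.82 ± 0.32 on the log2 scale (SD, n = 2 arrays), which is 113-fold, with limma adjusted p = 4.35e-08. Its raw signal was 835 in unexposed and 54400 in exposed RNA on replicate 1, and 751 and 43300 on replicate 2. The probe V7_6957 rose by 6.71 ± 0.21 (105-fold, limma adjusted p = 4.35e-08). The 15 probes with the highest ratio ran from 4.56 to 6.82 on the log2 scale. Among these 15, the ratio of 5 differed by more than 1 log2 unit between the arrays, and 3 were saturated in the exposed channel of replicate 1. With an intensity trend and a robust prior 4 of the 15 no longer passed the threshold, with limma adjusted p from 0.0747 to 0.185.

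Among the 15 probes with the lowest ratio the arrays lay closer together. The probe V7_10251 fell by 5.54 ± 0.13 on the log2 scale (SD, n = 2 arrays), a 46.6-fold decrease with limma adjusted p = 6.51e-08. Its raw signal was 13400 in unexposed and 122 in exposed RNA on replicate 1, and 12800 and 167 on replicate 2. The brightest negative control spot in that channel had 133. The probe's log2 ratio was -5.98 with an offset of 10 and -5.47 with no background subtraction, so the size of its decrease depends on the background correction. With the processed log ratio, which also differs in detrending and dye normalization, it was -6.36. The probe V7_1599 fell by 5.36 ± 0.12 (41.0-fold, limma adjusted p = 6.92e-08). The 15 probes with the lowest ratio ran from -5.54 to -4.60, and the arrays differed by no more than 1 log2 unit at any of them.

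Some probes were well above background on 1 side of the comparison only, which is not by itself a change. The unexposed RNA alone was well above background on both arrays at 668 probes, and the exposed RNA alone at 8. The unexposed channel was also the brighter one on both arrays. Of the 668 probes, only 280 were called lower, whereas the 8 were all called higher. These 280 were not well above background in exposed RNA on either array, so that their decrease has only a lower bound. That bound was taken against the higher of the probe's own level and the dimmest signal well above background on each array. It had a median of 1.58-fold over these probes and was 2-fold or more at 71 of them. At 139 of the 280 the own level set the bound on both arrays, so that it is the measured ratio itself. The bound allows neither for the spread between the arrays nor for a dye difference.

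**Figure D1:**
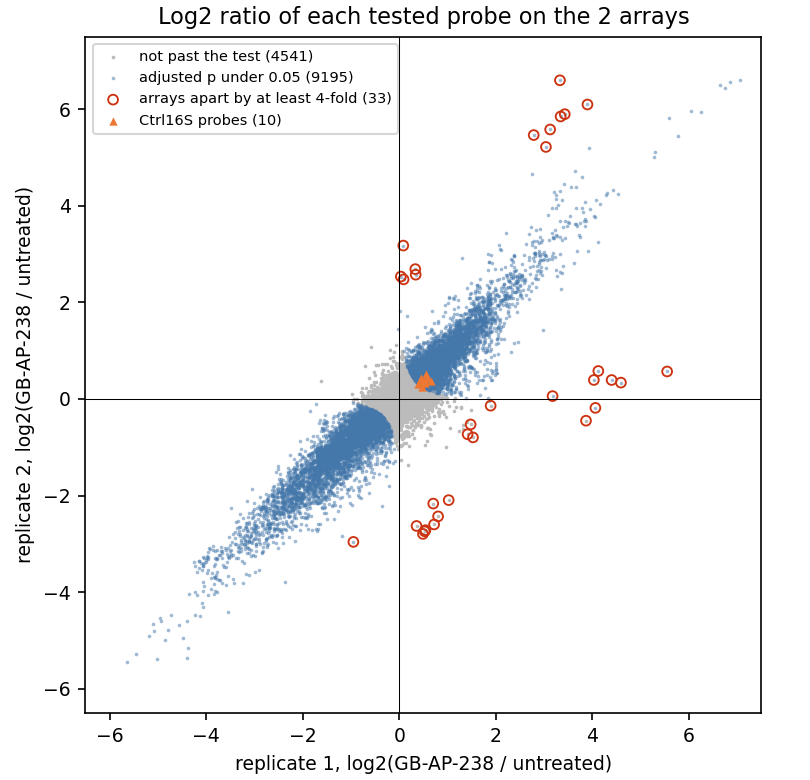
Log2 ratio of GB-AP-238 over untreated on replicate 1 (x axis) and replicate 2 (y axis), 1 point per tested probe (13736). Blue points passed limma at an adjusted p under 0.05 (9195), grey points did not, red circles mark the 33 probes whose ratio differed at least 4-fold between arrays, and orange triangles mark the 10 Ctrl16S probes, which lie above 0 on both arrays here (their median was -0.13 when centred on the E1A probes, where the median of all tested probes was -0.58).

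The 2 arrays ranked the probes alike. Across the tested probes, which are not independent replicates, the log2 ratios of replicates 1 and 2 correlated with Pearson r = 0.942 and Spearman rho = 0.929. Since the dyes ran the same way on both arrays, a dye difference of a probe can add to this agreement. The median difference between the arrays was 0.21 log2 units, and 11.1% of the tested probes had opposite signs. Fewer dim probes passed the threshold. With the probes in 10 groups by brightness, r was 0.758 in the dimmest group and 29.8% of it passed the threshold, whereas in the other groups r was at least 0.876 and between 53.9% and 77.8% passed. The ratios spanned less in the dimmest group, with an SD of 0.38 over its probes against at least 0.64 in the others, while the median SD between arrays was 0.12 there and 0.18 in the brightest group. With an offset of 10 in the background correction 44.4% of the dimmest group passed, with a median SD of 0.20, and with the processed log ratio 56.8%, with a median SD of 0.34.

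**Figure D2:**
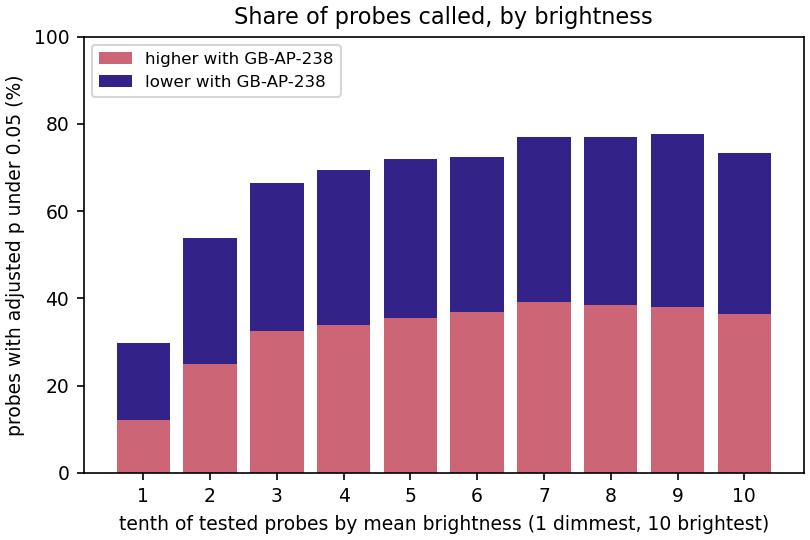
Percent of probes past an adjusted p of 0.05 (y axis) in each of 10 equal groups of the tested probes by mean brightness over both channels and arrays (x axis), stacked as higher (pink) and lower (dark blue) with GB-AP-238. The dimmest group reaches 29.8% (12.1% higher, 17.7% lower) and the highest bar 77.8% (38.0% higher, 39.8% lower).

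The ratios of a small set of probes differed widely between the arrays. At 33 of the 13736 probes the ratio differed at least 4-fold between the arrays, and 20 of these still passed the limma threshold. The ratio was higher on replicate 1 at 21 of them and higher on replicate 2 at 12. Among the 21, the median difference of the unexposed RNA level, replicate 1 minus replicate 2, was -3.48 log2 units, and the level of the exposed RNA differed between the arrays by a median of 0.19. Among the 12, the unexposed RNA was higher on replicate 1 by a median of 1.39 log2 units and the median difference of the exposed RNA was -1.13. Of the 33 probes, 9 had a saturated spot, against 237 of all 13736 tested.

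**Figure D3:**
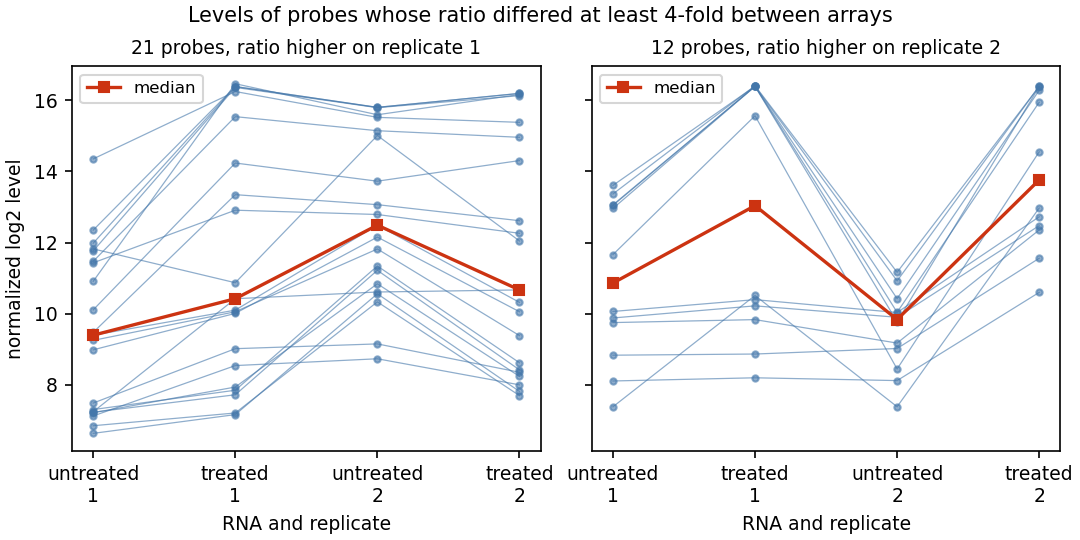
Normalized log2 level (y axis) of untreated and treated RNA on replicates 1 and 2 (x axis) for the 33 probes whose ratio differed at least 4-fold between arrays, with 1 blue line per probe and the median in red. At the 21 probes in the left panel the untreated RNA of replicate 1 minus that of replicate 2 has a median of -3.48 log2 units.

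With only 1 residual degree of freedom per probe, the test rests on the spread shared by all probes. In 20 simulations with 200 changed probes among 13736, a mean of 12.7% of the calls were wrong, above the nominal 5%. That share does not carry over to the real calls, since the simulations had far fewer changed probes. The 2-fold counts above use no test and do not depend on it.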

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

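The tests of explanations in this part, and measuring the Ctrl16S height from the median of all probes, were chosen after the results were seen, while the background and centring settings had been fixed beforehand. Signals were flagged in 2 sets of probes. The E1A probes are the array maker's control probes for spike-in RNA, and the labels do not mention that such RNA was added. Their median green signal was 794 on replicate 1 and 315 on replicate 2, against 245 for the brightest negative control spot, and 5 of the 10 were above every negative control spot in both channels of both arrays. The probes tagged Ctrl16S are 10 probes that the design sets apart by name, and their median log2 ratio of exposed over unexposed was 0.447.

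Both sets lay above the typical probe, but the Ctrl16S height is within the spread of other probes. Of 1894 other probes of the same brightness, 35.7% lay above the Ctrl16S median. The log2 ratios of those probes had a median of 0.07 and an SD of 1.27. All 10 Ctrl16S probes were above 0 on both arrays, with a mean of 0.45 ± 0.06 (SD over the 10 probes), and 8 of them passed limma's adjusted p of 0.05; of the 10 E1A probes, 9 were above 0 on both arrays and 1 below, with a median of 0.59. Centring on the E1A probes moved the Ctrl16S median to -0.13 and the median of all tested probes to -0.58. The height of the Ctrl16S median above the median of all tested probes was 0.448 in the main setting. Background correction as the whole cause is argued against, as the height was 0.453 with no background subtraction and 0.472 with an offset of 10. Whether the loess curve is the whole cause is not decided, because of the settings fixed beforehand only median centring lacked an intensity curve. It gave the lowest height, 0.328, so part of the height depends on the curve. The bound was 0.224 (0.5 of the main value), with an SD of 0.06 over the probes. That SD leaves out the spread between the arrays, whose Ctrl16S medians were 0.536 and 0.373 in the main setting. The measure was also changed after the results were seen: the height was first measured from 0, where the lowest value of 0.215 lies under the bound. Whether these probes read material other than the sample's messenger RNA stays open. Ctrl16S probes were brighter on replicate 1 by 2.14-fold (green) and 2.08-fold (red) and E1A probes by 2.45-fold and 1.80-fold. The tested probes had 1.19-fold and 0.972-fold. Of 1894 probes of the same brightness, 2.75% reached the least of the 10 Ctrl16S probes, 1.78-fold (green) and 1.73-fold (red). This test replaced a void one whose outcome the loess curve fixed, and it cannot decide the question. A brightness change shared by both channels cancels in the ratio, and the limits were taken from the same 10 probes. A transcript that differed in amount between the replicates would change in the same way. A dye difference of these probes cannot be told apart from a change of their transcripts, since 0 arrays had the dyes exchanged.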

How the results depend on the processing

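The 2-fold limit and the control-probe centrings moved a count by more than 1.5 times. With a mean change of at least 2-fold added to the threshold, 1564 probes were higher and 2450 lower, because fewer probes can qualify. Centring on the Ctrl16S probes, added after seeing the data, gave 1825 higher and 610 against 3282 probes at least 2-fold higher and lower on both arrays, in a fit with an infinite prior; the same shift on both arrays, also added, kept the prior and gave 2087 higher, 7348 lower, 619 and 3420. Centring on the E1A probes gave 1683 higher and 8144 lower, and 504 against 3889. All of these shift the ratios down by construction. The other settings kept each count within 1.5 times, with 3696 to 4578 probes higher and 4015 to 5455 lower. Median centring moved the median log2 ratio to -0.11 and gave 3696 higher and 5455 lower, and the processed log ratio, with which the series table is identical, gave 4527 and 4438. Of the probes higher and lower in the main setting, 4206 and 4143 were called the same way there. Pearson r stayed between 0.923 and 0.946. Replicate 1 alone had 1672 and 2594 probes at least 2-fold higher and lower, and replicate 2 alone 1523 and 2321; 1 array gives no test. The 30 probes under the naming rule kept their sign in every setting that held them. With an intensity trend and a robust prior 4 of them, all among the highest 15, no longer passed the threshold. These 4 belong to the 33 probes whose ratio differed at least 4-fold between the arrays, and the cause was not tested. Leaving out saturated spots removed 3 of the 30. Gene lists and the mean over a gene's probes were not run, since no probe has a gene here. Each array already sets exposed against unexposed RNA, so the main fit uses this pairing, and no further pairing could be fitted. In the dimmest of 10 brightness groups 29.8% of the probes passed the threshold. The share was 28.5% with no background subtraction and 44.4% with an offset of 10 (added after seeing the data), so it depends on the offset. With the processed log ratio, which also differs in detrending and dye normalization, the share was 56.8%.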

Other observations

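The tests of the discordant probes, the weighing of the 2-fold decreases and the turned sign were chosen after the results were seen, while the background, centring and filter settings had been fixed beforehand. Over the 4 RNAs, the 33 probes with discordant ratios had these profiles. At 10 probes the unexposed RNA of replicate 1 alone was low, at least 2-fold below each of the other RNAs. At 9 the unexposed RNA of replicate 2 alone was high, at 6 it alone was low, and at 6 the exposed RNA of replicate 2 alone was high. The exposed RNA of replicate 1 alone was high at 1 probe. Summed over these profiles, an unexposed RNA stood alone in 25 cases and an exposed one in 7. A probe can have more than 1 profile. V7_12483 was counted for both unexposed RNAs, and V7_10020 for an unexposed and an exposed one. Among all tested probes the counts were closer, 141 and 114. The widest gap was at a probe with a log2 ratio of 5.55 on replicate 1 and 0.57 on replicate 2, where the level in unexposed RNA was 10.91 and 15.59 and that in exposed RNA 16.46 and 16.16. This probe had 2 saturated spots, so the size of its gap is not exact.

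Detector saturation as the cause at most of these probes is argued against, since 72.7% of the 33 probes had no saturated spot. Saturation was still more common here, at 9 of the 33 against 237 of all 13736 tested probes. A part in some of the gaps is therefore not excluded. A local defect of one array cannot be told apart from other causes: the share of 1000 random sets of tested spots that lay as close together was 0.217, so no clustering was detected and none was excluded. In 81.8% of the probes (27 of 33, exact binomial 95% interval 64.5% to 93.0%) the unexposed level differed more between the arrays than the exposed level. Saturation limits the exposed level, and without saturated probes the share was 75% (18 of 24, interval 53.3% to 90.2%). The intervals treat probes as independent, which probes of 1 transcript are not. A candidate explanation is the untreated RNAs differing between replicates in a few variable transcripts, which stays a hypothesis, and the closer counts among all tested probes do not favour it.

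More 2-fold decreases than increases were found in each setting in which both were counted. The dimmer treated channel losing probes is argued against as the cause, because decreases were still 61.4% of the 2-fold changes (exact binomial 95% interval 59.7% to 63.0%) among the 12585 probes well above background in both channels. The choice of background correction is argued against too, because the lowest share over the background settings fixed beforehand was 59.2%. The choice of centring cannot be told apart from a stronger fall than rise of transcripts: no probe is known to be unchanged, a shift of all log2 ratios by 0.17 would even the counts, and the share was 73.1% with median centring, 84.3% centred on the Ctrl16S probes and 88.5% centred on the E1A probes. A dye difference stays open and was not tested.

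The 2 arrays allow 2 sign patterns, too few for a share under 0.05. The real pattern gave 9195 probes past the limma threshold, and the pattern with 1 array turned gave 0, also 0 at an unadjusted p under 0.05. Turning 1 array moves the ratio that the arrays share into the spread between them. With arrays that correlate at r = 0.942, few calls can then remain. The 0 therefore does not show how many calls would arise without an effect.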
